A study of Bos taurus with 11 samples.

How the data were processed

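Mammary tissue of untreated Holstein heifers aged 10 to 12 months was sequenced after poly A selection, per the labels. Each sample came from 1 of 3 regions of the gland, named parenchyma, close stroma and far stroma in the labels, which give no distances between them. Parenchyma and far stroma were taken from heifers 1, 3, 4 and 5 (n = 4 each) and close stroma from heifers 3, 4 and 5 (n = 3), so that 11 samples came from 4 animals, 3 of which gave all 3 regions. The column of 1 sample has a name that ends in a letter the labels do not explain. It was taken as the close stroma of heifer 4, which the rest of the name gives, and results without that sample stand beside the counts. Per the labels' protocols, tissue was stored in a solution that preserves RNA, RNA was extracted with a phenol-based reagent and fragmented, and the complementary DNA received adapters and barcodes and was amplified by PCR. The submitters' processing notes name cutadapt, STAR, HTSeq and DESeq2 and the bovine build ARS-UCD1.2, without versions, settings or roles. Whether strand was used in counting, and how genes were filtered, is not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be separated further, nor can those of any close paralogs.

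The deposited table holds a signal per gene and sample that the authors headed as normalised counts, for 16279 genes, of which 14300 carry a symbol and 1979 an Ensembl identifier only. 47 symbols stand on more than 1 line of it. In each sample, 100% of the values lay within 0.01 of a whole multiple of the value of 1 read, so that each value is a whole read count divided by 1 size factor per sample, and the read counts were recovered from these steps. The recovered totals ran from 7274474 to 11156909 reads per sample. The lowest total of a gene over all samples was 3 reads, so low values rest on few reads. A second deposited sheet holds thresholds of the authors (adjusted p of at most 0.05, absolute log2 fold change of at least 1 and a highest normalised count of at least 30). Fold changes or p-values of the authors were not used here.

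The normalised values were tested as log2(value + 1) with limma (version 3.58.1 in R 4.3.3), with a trend of the variance on the mean, in 1 fit of 3 groups that share an estimate of the spread. Genes whose highest group mean was 10 or more were tested (14596 genes). The design had foreseen edgeR for raw counts and limma for normalised values, and the latter applied. Log2 differences are on the log2(value + 1) scale, which understates the change of low genes, and are given with standard errors. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes were called at an adjusted p under 0.05. Means are given with SDs over animals, in normalised counts. Where a group held 1 to 3 reads of a named gene in all, the ratio of pooled reads is given with its 95% counting interval, and a group with 0 reads is set to a floor of 3 reads over the group. These intervals cover counting error only, since PCR copies were not distinguished.

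The numbers in the labels name the animals, so they pair the samples. Deviations from the group means correlated at 0.117 to 0.383 in the 10 pairs of samples from the same heifer and at -0.349 to 0.224 in the 30 pairs from different heifers, 5 of which lay above the lowest value of the former. The fit without the heifer as a block was the main one, as fixed in advance, and the fit with it is given beside the count of genes of each comparison, and elsewhere where it changes a call or moves a count by over 1.5 times.

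The gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 6 genes in each direction with the largest log2 difference among called genes with a symbol, groups that did not overlap and a mean of at least 50 in the higher group. It added 10 fixed genes (EPCAM, KRT8, KRT14, ESR1, PGR, ADIPOQ, PLIN1, LEP, COL1A1 and IGF1) and up to 4 members of each list with the smallest p. Any other gene named below was chosen after its values were seen, either as a further called member of a list or in the closing section. The 26 lists covered luminal epithelium, basal and myoepithelial cells, hormone receptors and responsive genes, milk and secretory proteins, the cell cycle, adipocytes, fatty acid and triglyceride synthesis, fibroblasts and fibrillar collagen, basement membrane, matrix proteases and inhibitors, paracrine growth factors, insulin-like growth factor (IGF) binding proteins, WNT and Notch signalling, and stem and progenitor markers. They also covered blood endothelium, lymphatic endothelium, smooth muscle and pericytes, skeletal muscle, nerve and Schwann cells, T and NK cells, B and plasma cells, macrophages, mast cells and granulocytes, erythrocytes, interferon-stimulated genes, and immediate early and stress genes. The lists held 9 to 27 genes, and THY1, CDH5 and KIT each stand on a pair of them. Lists with at least 3 measured members were tested against the remaining genes with camera (in limma) at a preset correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation and fry. Members were counted by their adjusted p over all genes tested and adjusted over the list alone.

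The position of close stroma between the other regions was computed per heifer as the median of (close minus far)/(parenchyma minus far) on the log2 scale, over genes called with at least a 2-fold change between parenchyma and far stroma. It is a description without a test.

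The procedure was tested on simulated reads, drawn with the mean of each gene over all samples, its dispersion and the real library sizes, with 99 or 100 genes changed at each size. For parenchyma against far stroma, 27.3% of genes changed by 1 on the log2 scale were called and 89% of those changed by 2. There were 6 calls among 14184 unchanged genes. Parenchyma against close stroma gave 17.2% and 82%, with 5 among 14182, and close against far stroma 20% and 86%, with 1 among 14181. The moved list was called in all 3 simulations and 0 others were. No correlation between genes or heifer effect was simulated, so false calls under these were not tested. With few genes changed, the shares need not hold where 50.1% were called.

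Alternatives covered other filters on low values, pseudocounts of 0.5 and 5, the heifer block, only the groups compared, heifer 1 left out, each sample left out in turn, a threshold of 0.01, the authors' thresholds and other list tests. Chosen after the data had been seen were edgeR (4.0.16) and DESeq2 (1.42.0) on the recovered reads, TMM and library-total scaling, and limma without the trend. Values named as from edgeR have TMM scaling unless RLE is named. With TMM, edgeR called 3490 genes higher and 3752 lower in parenchyma than in far stroma, 269 and 958 against close stroma, and 1566 and 653 in close against far stroma. A RefSeq gene table of the assembly ARS-UCD2.0 was used only for which genes neighbour each other. 0 of the file's Ensembl identifiers matched it, so symbols are those of the deposited table and no coordinates are given. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.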

Results

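Messenger RNA of mammary tissue was compared between parenchyma, the part of the gland that holds the ducts, close stroma and far stroma of heifers. The series title gives the comparison of stromal and parenchymal regions as its subject. Recovered reads numbered 11156909, 9924477, 8994156 and 9774620 in the parenchyma of heifers 1, 3, 4 and 5. They numbered 10557937, 9190163, 10431459 and 7274474 in their far stroma, and 10312840, 8965465 and 9131269 in the close stroma of heifers 3, 4 and 5. The most abundant gene took 0.666 to 1.9% of the reads of a sample. It was SPARC or GSN in the far stroma samples, SPARC in the close stroma of heifer 3, CD74 in 4 of the other samples, PAEP (beta-lactoglobulin) in the parenchyma of heifer 1 and CSN2 (beta-casein) in the close stroma of heifer 5. Between 672 and 1128 genes were at 0 in the far stroma samples, 233 to 337 in close stroma and 262 to 361 in parenchyma.

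The regions separated along the first principal component, which held 70.2% of the variance. Far stroma lay at -127.3 to -102.6 and parenchyma at 92.69 to 104. The close stroma samples of heifers 3, 4 and 5 lay between them at -15.81, 51.17 and 33.52. Across genes, Spearman correlations were 0.947 to 0.979 within far stroma, 0.946 to 0.975 within close stroma and 0.962 to 0.975 within parenchyma. They were 0.776 to 0.831 between far stroma and parenchyma, 0.861 to 0.957 between far and close stroma, and 0.887 to 0.96 between close stroma and parenchyma, where genes are not independent replicates.

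**Figure D1:**
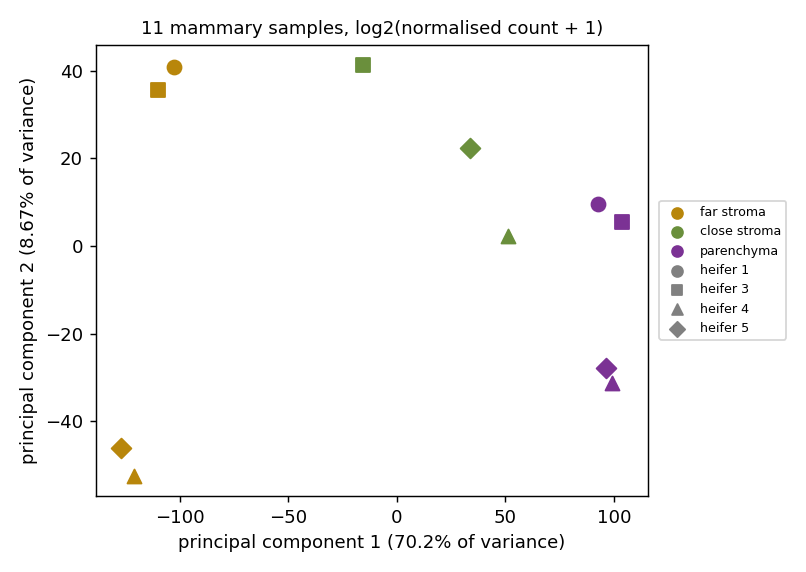
Each point is 1 of the 11 samples, placed by the first (70.2% of variance) and second (8.67%) principal components of log2(normalised count + 1), with colour for the region and marker shape for the heifer. Regions separate on the first component.

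Parenchyma and far stroma differed in all 22 luminal epithelium genes and in 17 of 19 adipocyte genes. Keratin 8 (KRT8, ENSBTAG00000000836), a filament protein of simple epithelia, averaged 3335 ± 366.5 normalised counts in parenchyma and 8.75 ± 5.64 in far stroma (SD, n = 4 each, log2 difference 8.60 ± 0.35 SE). Leptin (LEP), a hormone of fat cells, averaged 9.64 ± 1.74 in parenchyma and 5554 ± 1938 in far stroma (log2 -8.97 ± 0.38). By camera, the lists of T and NK cells and of B and plasma cells were higher in parenchyma, and those of fatty acid and triglyceride synthesis, fibroblasts and blood endothelium were lower. These 5 calls did not hold with an estimated correlation (adjusted p = 0.277, 0.304, 0.277, 0.423 and 0.277 in that order). Of 14596 genes tested, 3805 were higher and 3501 lower in parenchyma, which is 50.1% of them, and 2568 and 2135 of these differed at least 2-fold. With the heifer as a block the counts were 4103 and 3686. The balance depended on the scaling, since with each library scaled to its total 6366 genes were higher and 2093 lower (75.3% higher against 52.1%), with the median of all genes shifted by 0.42 on the log2 scale. On the recovered reads, edgeR gave 3490 higher and 3752 lower (48.2% higher) with TMM scaling and 3677 and 3558 (50.8% higher) with RLE scaling.

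The 6 genes with the largest rise by the fixed rule were PIGR, SLC28A3, SERPINA1, FOXA1, CYP11A1 and SPINT1, each higher in parenchyma in 4 of 4 heifers. PIGR (ENSBTAG00000019798), the receptor that carries polymeric immunoglobulins across epithelia, averaged 5607 ± 3125 in parenchyma and 4.73 ± 4.99 in far stroma (log2 10.16 ± 0.61, limma adjusted p = 7.93e-08). The nucleoside transporter SLC28A3 averaged 1854 ± 716.6 and 1.03 ± 1.39 (log2 10.01 ± 0.42), the protease inhibitor SERPINA1 4169 ± 2692 and 4.25 ± 3.69 (9.76 ± 0.67), and the epithelial protease inhibitor SPINT1 2345 ± 669.4 and 2.71 ± 2.36 (9.55 ± 0.53). FOXA1, a transcription factor of hormone-responsive luminal cells, had 2 reads in the far stroma group and a pooled ratio of 2150 (95% counting interval 596 to 17800). CYP11A1, the enzyme that starts steroid synthesis from cholesterol, had 3 reads there and a ratio of 1660 (567 to 8030). Lowest in parenchyma relative to far stroma were S100G, THRSP, LEP, RXRG, CIDEC and TRARG1, in 4 of 4 heifers each. S100G, a calcium-binding protein, averaged 2.11 ± 2.36 and 4115 ± 2816 (log2 -10.48 ± 0.59), and THRSP, a regulator of lipogenesis, 33.2 ± 18.2 and 22090 ± 14160 (-9.16 ± 0.81). The nuclear receptor RXRG had a log2 difference of -8.81 ± 0.48, the lipid droplet protein CIDEC -8.76 ± 0.34 and TRARG1, which acts in the traffic of the glucose transporter GLUT4, -8.56 ± 0.36.

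All 22 luminal epithelium genes were higher in parenchyma. Median log2 was 7.50 over the list, or 7.94 with 4 low-read members set to their ratios (camera adjusted p = 3.04e-19, and adjusted p = 0.106 with an estimated correlation). Examples were KRT7 at 5843 ± 759.5 against 9.13 ± 4.17 (log2 9.26 ± 0.28), the tight junction protein CLDN3 (8.10 ± 0.26) and EPCAM, an epithelial adhesion molecule, at 1997 ± 355.1 against 90.5 ± 31.3 (4.51 ± 0.35). Among 19 basal and myoepithelial genes, 16 were higher and 3 did not pass. Median log2 was 5.70 over the list (adjusted p = 1.38e-09, and adjusted p = 0.147 with an estimated correlation). KRT5 averaged 3554 ± 298.1 against 6.02 ± 2.48, the hemidesmosome collagen COL17A1 7913 ± 2281 against 9.51 ± 0.77, and KRT14 had 2 reads in far stroma and a pooled ratio of 987 (273 to 8150). Of 17 hormone receptors and responsive genes, 10 were higher, 1 lower and 6 did not pass. Median log2 was 2.80 over the list (adjusted p = 0.00142, and adjusted p = 0.277 with an estimated correlation). GATA3, a luminal transcription factor, averaged 1505 ± 257.2 against 54.1 ± 12.1, TNFSF11 (the ligand RANKL) had a log2 difference of 4.75 ± 0.43, and the progesterone receptor PGR averaged 230.9 ± 115.5 against 31.8 ± 12.6 (2.80 ± 0.58, adjusted p = 0.00156). The growth hormone receptor GHR was the member lower in parenchyma (-1.92; 2 lower without the far stroma of heifer 3). The oestrogen receptor ESR1 did not pass (684.9 ± 233 against 520.7 ± 416.2, log2 0.76 ± 0.50, adjusted p = 0.226, higher in 3 of 4 heifers), and passed at 0.0328 without the far stroma of heifer 1.

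Milk and secretory proteins were higher for 8 of 18 members, with 10 not passing (11 higher with the heifer block, 13 by edgeR and 12 by DESeq2). Median log2 was 4.77 over the list (adjusted p = 0.00156, and adjusted p = 0.423 with an estimated correlation). Lactoferrin (LTF) averaged 47800 ± 24910 in parenchyma and 86.6 ± 18.9 in far stroma (log2 8.91 ± 0.44), and kappa-casein (CSN3) 16430 ± 20440 and 52.4 ± 50.3 (7.93 ± 0.85), each in 4 of 4 heifers. The spread between heifers was wide for the major milk proteins. CSN2 was at 99100, 5480, 126 and 109 in the parenchyma of heifers 1, 3, 4 and 5 and at 349, 21.6, 36.1 and 96.8 in their far stroma (log2 4.50, adjusted p = 0.105, and 0.0374 with the heifer block). PAEP was at 119000, 7330, 66.8 and 233 in parenchyma (5.04, adjusted p = 0.0682, and 0.0192 with the heifer block), while KRT8 lay between 2870 and 3750 in the same samples. Of 22 cell cycle genes, 20 were higher in parenchyma and 2 did not pass. Median log2 was 1.88 over the list (adjusted p = 6.56e-05, and adjusted p = 0.395 with an estimated correlation). The proliferation marker MKI67 averaged 512.1 ± 286.6 against 65.1 ± 50.1 (log2 3.16 ± 0.56), the mitotic regulator CDC20 had a difference of 2.88 ± 0.50, and the kinase PLK1 1.37 ± 0.19.

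**Figure D2:**
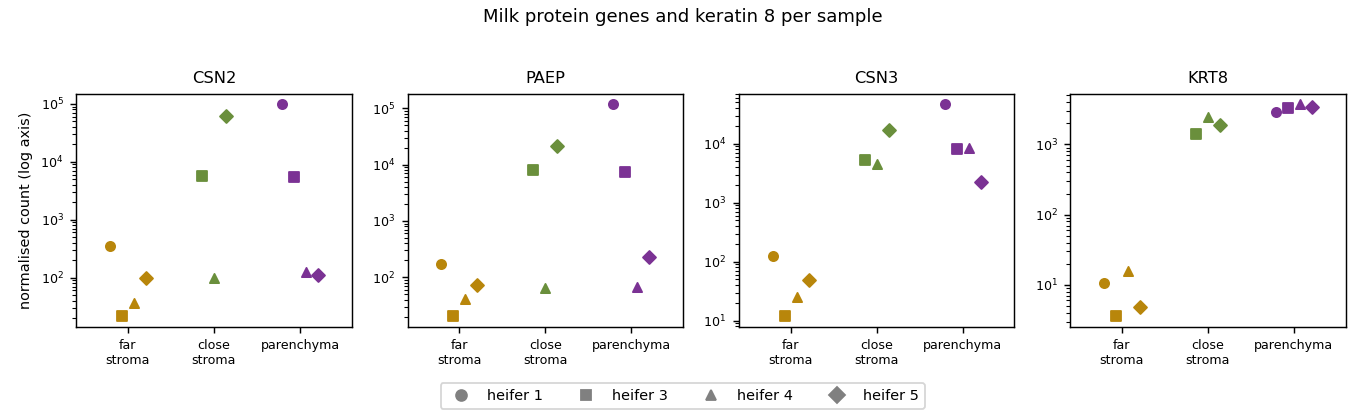
Normalised counts (log axis) of CSN2, PAEP, CSN3 and KRT8 in each sample, grouped by region, with a marker shape for each heifer. CSN2 in parenchyma runs from 109 to 99100 while KRT8 stays between 2870 and 3750.

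Of 19 adipocyte genes, 17 were lower in parenchyma and 2 did not pass. Median log2 was -6.45 over the list (adjusted p = 5.37e-15, and adjusted p = 0.212 with an estimated correlation). Adiponectin (ADIPOQ) averaged 49.5 ± 13.1 in parenchyma and 9740 ± 1382 in far stroma (-7.62 ± 0.33), the lipid droplet coat protein PLIN1 173.4 ± 11.2 and 47360 ± 3315 (-8.08 ± 0.32), and hormone-sensitive lipase (LIPE) differed by -7.77 ± 0.33. Of 17 genes of fatty acid and triglyceride synthesis, 15 were lower and 2 did not pass. Median log2 was -2.60 over the list (adjusted p = 1.62e-06, and adjusted p = 0.277 with an estimated correlation). Among them were stearoyl-CoA desaturase (SCD, 1694 ± 997 against 95920 ± 69130), GPD1 (-6.10 ± 0.41) and the malic enzyme ME1 (-4.72 ± 0.34). Fibroblast and fibrillar collagen genes were lower for 16 of 21 members (17 when adjusted over the list alone, 9 with library-total scaling), with TNC (tenascin C, 1.40; 2 higher without the parenchyma of heifer 3) higher and 4 not passing. Median log2 was -1.41 over the list (adjusted p = 1.58e-04, and adjusted p = 0.423 with an estimated correlation). Decorin (DCN) averaged 18520 ± 2015 against 59430 ± 8395 (-1.68 ± 0.22) and the collagen cross-linking enzyme LOX differed by -3.66 ± 0.47. Collagen I (COL1A1, -1.73 ± 0.64, adjusted p = 0.0384, lower in 3 of 4 heifers) did not pass without the far stroma of heifer 1, 3 or 4 (0.0738, 0.0889, 0.0693) or the parenchyma of heifer 3 or 4 (0.115, 0.108).

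**Figure D3:**
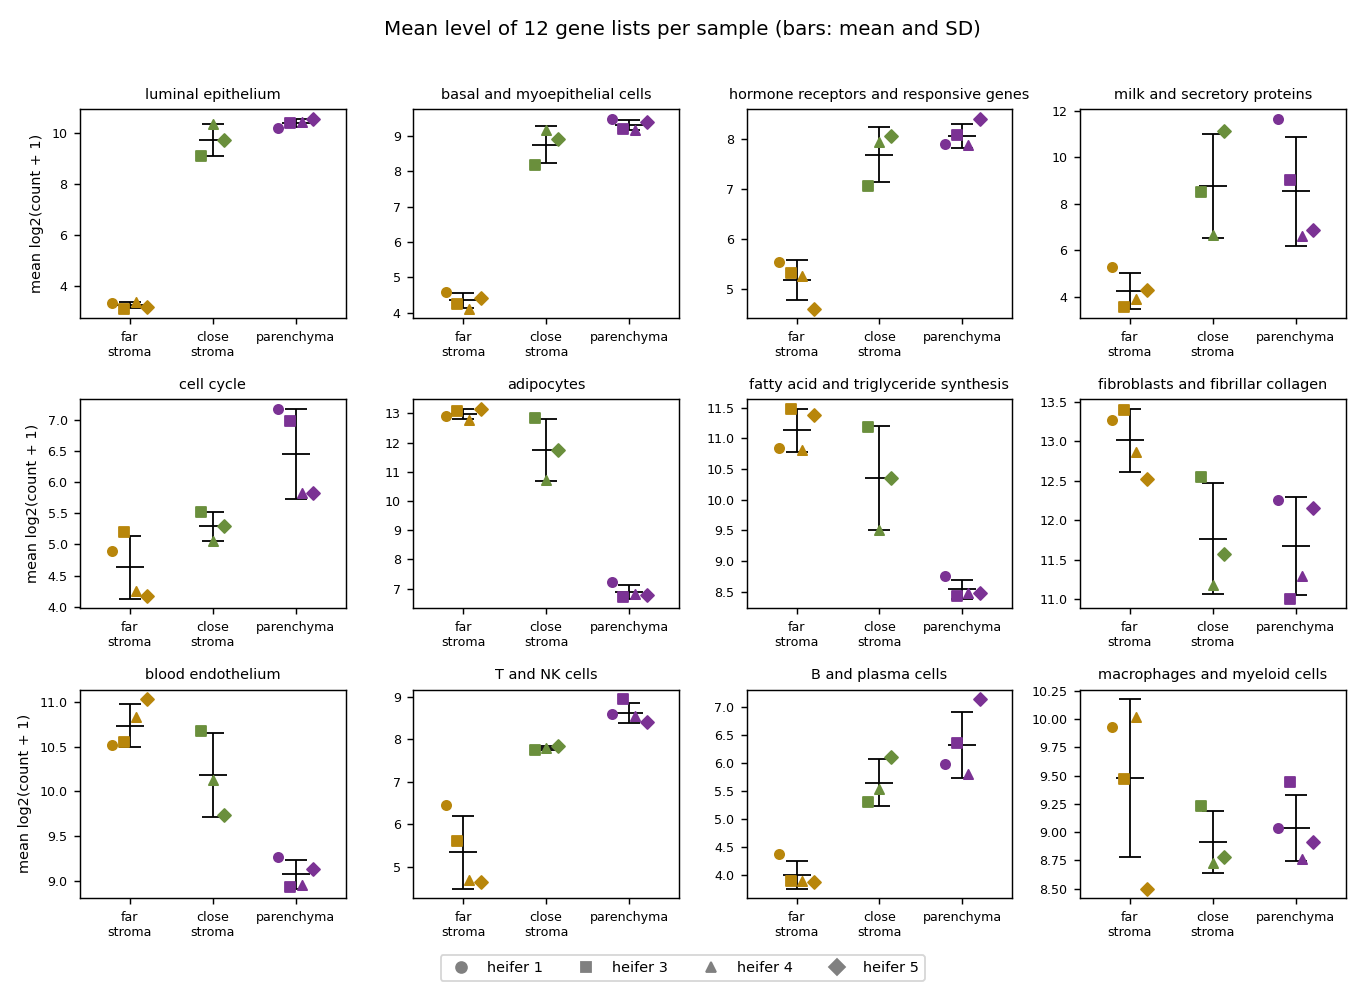
Mean log2(normalised count + 1) of the members of 12 gene lists in each sample, by region, with a marker shape per heifer and bars for the mean and SD of each region. The luminal list lies at 3.1 to 3.35 in far stroma, 9.09 to 10.35 in close stroma and 10.21 to 10.57 in parenchyma, and the adipocyte list at 12.76 to 13.15, 10.7 to 12.83 and 6.72 to 7.22.

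Matrix proteases and inhibitors were lower for 7 of 14 members (8 when adjusted over the list alone) and higher for MMP11 (1.99 ± 0.33; 2 higher with the heifer block or by edgeR, 3 by DESeq2 or with library-total scaling, 2 without the parenchyma of heifer 1), with 6 not passing. Median log2 was -1.06 over the list (adjusted p = 0.0145, and adjusted p = 0.372 with an estimated correlation). The inhibitors TIMP4 (-3.88 ± 0.31) and TIMP2 (-3.37 ± 0.33) were among those lower. The remaining signalling and matrix lists went both ways and did not pass camera. Basement membrane genes were higher for 5 and lower for 8 of 14 (median -1.07, mean -0.17, adjusted p = 0.214), with AGRN (agrin) at 2.50 ± 0.23, COL4A5 at 2.77 ± 0.34 and the laminin chain LAMB2 at -2.49 ± 0.27. Paracrine growth factors were higher for 4 and lower for 7 of 21, a balance that turned to 7 and 6 with library-total scaling (lower for 9 when adjusted over the list alone, median -0.41, adjusted p = 0.176). FGF1 (-4.56 ± 0.38), FGF2 (-2.26 ± 0.21) and BMP2 (-2.72 ± 0.23) were lower, and the neuregulin NRG1 was higher (4.79 ± 0.48). IGF binding proteins and their axis were higher for 2 and lower for 4 of 12 (median -0.81, adjusted p = 0.0755), with IGFBP6 at -3.67 ± 0.38, IGFBP5 at 653.6 ± 290.1 against 5192 ± 2252 normalised counts and IGF1 not passing (0.11 ± 0.59, adjusted p = 0.889, higher in 2 of 4 heifers). The 4 lower members became 2 without the far stroma of heifer 4 or the parenchyma of heifer 3 or 4, and 2 with library-total scaling.

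WNT and Notch genes were higher for 14 and lower for 7 of 26. Median log2 was 0.64 over the list (adjusted p = 0.0901). WNT5B (3.12 ± 0.24), WNT6 (4.11 ± 0.35) and the WNT effector LEF1 (3.07 ± 0.32) were higher, while the receptor FZD4 was lower (390.4 against 3269 normalised counts). Stem and progenitor markers were higher for 3 and lower for 6 of 16, a balance that turned to 5 and 4 with library-total scaling. Median log2 was -0.09 and mean 0.18 over the list (camera direction down, adjusted p = 0.498). SOX10 averaged 5584 ± 288.1 against 69.5 ± 10.6 (log2 6.32 ± 0.19), SOX9 differed by 5.26 ± 0.55, and PROCR by -3.26 ± 0.34.

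Blood endothelium genes were lower in parenchyma for 16 of 17 members. Median log2 was -1.61 over the list (adjusted p = 2.45e-08, and adjusted p = 0.277 with an estimated correlation). PECAM1, an adhesion molecule of vessel walls, averaged 1087 ± 114.4 against 3744 ± 276.9 (-1.79 ± 0.20), and the junction protein CLDN5 differed by -2.94 ± 0.35. Lymphatic endothelium genes were lower for 4 of 9, among them LYVE1 (-3.21 ± 0.36), and higher for the chemokine CCL21 (1.02; 2 higher with library-total scaling). Median log2 was -0.13 over the list (adjusted p = 0.192). Smooth muscle and pericyte genes were higher for 4 and lower for 4 of 13 (median -0.07, mean 0.16, adjusted p = 0.804), with MYH11 at 2.85 ± 0.33 and the pericyte channel KCNJ8 at -1.66 ± 0.21, and 6 and 4 with library-total scaling. Of 4 measured skeletal muscle genes, TNNT3 (1.60) and ATP2A1 (1.10) were higher and myoglobin (MB, -3.25; 2 lower by DESeq2 or without the far stroma of heifer 1, 3 or 5) lower. Median log2 was 0.66 and mean -0.08 over the list (adjusted p = 0.715). Nerve and Schwann cell genes were lower for 7 of 11, such as S100B (-2.20 ± 0.25) and PMP22 (-1.79 ± 0.22), and higher for MBP (2.09) and ERBB3, a neuregulin receptor also made by epithelium (5.81 ± 0.35). Median log2 was -1.79 over the list (adjusted p = 0.0755).

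All 16 T and NK cell genes were higher in parenchyma. Median log2 was 3.34 over the list (adjusted p = 5.76e-09, and adjusted p = 0.277 with an estimated correlation). CD3E, part of the T cell receptor complex, averaged 2012 ± 252.6 against 144.7 ± 102.4 (4.03 ± 0.35) and the kinase ZAP70 826.8 ± 170.4 against 81.3 ± 5.48 (3.31 ± 0.19), each in 4 of 4 heifers. B and plasma cell genes were higher for 13 of 15 (median 2.63, adjusted p = 7.70e-04, and adjusted p = 0.304 with an estimated correlation), such as CD79A (283 ± 125.6 against 8.69 ± 2.99) and JCHAIN (4.34 ± 0.49), while the complement receptor CR2 was lower (-4.78; 2 lower when adjusted over the list alone, by edgeR, by DESeq2 or without the far stroma of heifer 3). Macrophage and myeloid genes were higher for LYZ (1.64 ± 0.41) and lower for 3 of 16 (2 when adjusted over the list alone, 2 higher and 5 lower with the heifer block, 6 lower by edgeR and by DESeq2), a balance that turned to 4 and 2 with library-total scaling and to 3 and 2 without the far stroma of heifer 4. Median log2 was -0.39 over the list (adjusted p = 0.26). Without the far stroma of heifer 5, 8 members were lower and the list passed at 0.0271 (with all samples, adjusted p = 0.737 with an estimated correlation). The scavenger receptor CD163 averaged 104.8 ± 32.7 against 1562 ± 780.2 (-3.77 ± 0.46). Mast cell and granulocyte genes were lower for 4 of 12, such as CPA3 (-3.98 ± 0.42), with adjusted p = 0.0583, 0.041 with the heifer block and 0.016 without the parenchyma of heifer 5 (median -0.66; adjusted p = 0.439 with an estimated correlation, and 0.415 with the block too).

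Interferon-stimulated genes were higher for 5 and lower for 3 of 16 (9 and 1 with library-total scaling; median 0.55, adjusted p = 0.235), with IFI44L at 2.83 ± 0.25 and RSAD2 at -1.24 ± 0.29. Immediate early and stress genes, which respond within minutes to stimuli, were lower for 10 of 19 (6 with library-total scaling) and higher for EGR2 (3.49 ± 0.62) and EGR3 (1.41). The list passed camera (median -0.73, adjusted p = 0.0237, and adjusted p = 0.51 with an estimated correlation), but not without the far stroma of heifer 1 (0.0563). KLF4 averaged 489.6 ± 86.5 against 4057 ± 1220 (-3.01 ± 0.27) and DUSP1 differed by -2.73 ± 0.36. Of the erythrocyte list, 2 members were measured and the list was not tested. HBA was lower in parenchyma (-2.95 ± 0.92, adjusted p = 0.0175, lower in 4 of 4 heifers), but not without the parenchyma of heifer 1 (0.0519) or 4 (0.0548), nor by edgeR or DESeq2, and HBB did not pass (-0.28 ± 1.16, adjusted p = 0.859, lower in 3 of 4 heifers).

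Parenchyma and close stroma differed in 17 of 19 adipocyte genes, which were higher in close stroma. ADIPOQ averaged 49.5 ± 13.1 in parenchyma (n = 4) and 6091 ± 3499 in close stroma (n = 3; log2 -6.75 ± 0.36, adjusted p = 4.05e-07, lower in 3 of 3 heifers). KRT8 averaged 3335 ± 366.5 and 1938 ± 531.6, a difference that did not pass (0.81 ± 0.37, adjusted p = 0.211, higher in 3 of 3 heifers). By camera, the blood endothelium list was lower in parenchyma (11 of 17 members passing), as was the immediate early and stress list (3 of 19), and the lists of T and NK cells (2 of 16) and the cell cycle (2 of 22) were higher. These 4 calls did not hold with an estimated correlation (adjusted p = 0.223, 0.448, 0.448 and 0.438 in that order). In all, 295 genes were higher and 744 lower in parenchyma (7.12% of 14596), of which 166 and 629 differed at least 2-fold, and 496 and 953 passed with the heifer block. The counts depended on single samples. Without the close stroma of heifer 3, 4 or 5 they were 53 and 326, 340 and 912, and 98 and 484, and without the parenchyma of heifer 1, 3, 4 or 5 they were 167 and 621, 106 and 483, 113 and 476, and 147 and 573.

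The largest rises in parenchyma were in GDF10, COL26A1, PLA2G5, VIPR1, ERN2 and CACNA1G, in 3 of 3 heifers each. GDF10, a growth factor of the TGF-beta family, averaged 776 ± 250.8 against 60.3 ± 47.6 in close stroma (log2 3.91 ± 0.62, adjusted p = 0.00267). The collagen gene COL26A1 differed by 2.83 ± 0.54, the secreted phospholipase PLA2G5 by 2.72 ± 0.45 and VIPR1, a receptor of vasoactive intestinal peptide, by 2.66 ± 0.46. ERN2 (2.63 ± 0.59, adjusted p = 0.0193) did not pass without the close stroma of heifer 3 (0.089) or the parenchyma of heifer 3 (0.0641) or 5 (0.057). The calcium channel gene CACNA1G (2.57 ± 0.61, adjusted p = 0.0234) did not pass without the close stroma of heifer 4 (0.0675) or 5 (0.0725) or the parenchyma of heifer 1 (0.054), 4 (0.0611) or 5 (0.0574). Lowest in parenchyma were the 6 genes that were also lowest against far stroma, with S100G at 2.11 ± 2.36 against 1148 ± 586.2 (-8.68 ± 0.63), THRSP at -7.68 ± 0.87, LEP at -7.38 ± 0.41, RXRG at -7.37 ± 0.52, CIDEC at -7.19 ± 0.37 and TRARG1 at -7.13 ± 0.39.

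Luminal epithelium genes were higher as a list (median log2 0.71, adjusted p = 4.86e-04, and adjusted p = 0.448 with an estimated correlation), but not without the close stroma of heifer 3 (0.0523). By fry the adjusted p of this list was 0.0979. By limma, 0 of the 22 members passed, against 4 at an unadjusted p under 0.05, 0 by edgeR, 3 by DESeq2 and 1 without the close stroma of heifer 4. EPCAM differed by 0.39 ± 0.38. Of 19 basal and myoepithelial genes NGFR, the low-affinity nerve growth factor receptor, was higher (2300 ± 380.6 against 698.8 ± 30.6, adjusted p = 0.0208), and 2 members passed with the heifer block, 3 by DESeq2 and 4 without the close stroma of heifer 4, where LAMB3 (0.0332) and ITGB4 (0.0255) were gained (list median 0.72, adjusted p = 0.00933, and adjusted p = 0.448 with an estimated correlation). The list did not pass without the close stroma of heifer 3 (0.108). NGFR did not pass without the close stroma of heifer 3 (0.0903) or 5 (0.062) or the parenchyma of heifer 4 (0.0578) or 5 (0.0576). KRT14 did not pass (1.04 ± 0.42, adjusted p = 0.152). Of 17 hormone receptors and responsive genes GHR was lower (-1.51 ± 0.31, adjusted p = 0.0122, and 0.054 without the close stroma of heifer 3). Median log2 was 0.40 over the list (adjusted p = 0.407). ESR1 (0.13 ± 0.54) and PGR (0.40 ± 0.63) did not pass. Among 18 milk and secretory genes 0 passed by limma, against 1 at an unadjusted p under 0.05, 1 by edgeR and 0 by DESeq2 (median -0.05, mean -0.22, camera direction up, adjusted p = 0.849), and PIGR (2.07 ± 0.66, adjusted p = 0.0795) passed with the heifer block (0.00816). Cell cycle genes were higher as a list. Median log2 was 1.25 over the list (adjusted p = 1.53e-07, and adjusted p = 0.438 with an estimated correlation). PLK1 (1.24 ± 0.20, adjusted p = 0.00303) and MCM2 were the 2 members that passed of 22 (6 when adjusted over the list alone, 5 with the heifer block, 15 by DESeq2 and 16 at an unadjusted p under 0.05), and 1 passed without the close stroma of heifer 3 or 5 or the parenchyma of heifer 1 or 3. MCM2 (0.83 ± 0.21, adjusted p = 0.0329) did not pass without any 1 of the close stroma samples or the parenchyma of heifer 1, 3 or 4 (0.0517 to 0.13).

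Adipocyte genes were lower for 17 of 19 members (median -4.85, adjusted p = 5.16e-32, and adjusted p = 0.09 with an estimated correlation), with PLIN1 at 173.4 ± 11.2 against 22680 ± 15900 (-6.78 ± 0.34) and LIPE at -6.53 ± 0.36, in 3 of 3 heifers. Of 17 fatty acid and triglyceride genes 8 were lower (12 when adjusted over the list alone), such as GPD1 (-4.66 ± 0.44), SCD (-4.37 ± 0.75) and ME1 (-3.08 ± 0.37). Median log2 was -1.83 over the list (adjusted p = 3.09e-09, and adjusted p = 0.21 with an estimated correlation). That count became 4 without the close stroma of heifer 3 or 5 and 5 without the parenchyma of heifer 3 or 4. Of 21 fibroblast genes LOX was lower (-2.39 ± 0.50, adjusted p = 0.0139, and 0.0727 without the close stroma of heifer 3; 2 members with the heifer block or without the close stroma of heifer 4, 3 by DESeq2), and the list did not pass. Median log2 was 0.15 and mean -0.09 over the list (adjusted p = 0.837). COL1A1 differed by 0.55 ± 0.69. Matrix proteases and inhibitors were lower as a list (median -0.92, adjusted p = 0.00712, and adjusted p = 0.448 with an estimated correlation), with TIMP4 (-2.78 ± 0.33) and TIMP2 (-1.93 ± 0.35) as the 2 of 14 members that passed (1 higher and 6 lower when adjusted over the list alone or by DESeq2, 5 lower with the heifer block).

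Paracrine growth factors were lower for 4 of 21, among them FGF1 (-3.16 ± 0.41), FGF2 (-1.72 ± 0.22) and BMP2 (-1.78 ± 0.25; 1 higher with the heifer block). Median log2 was -0.10 over the list (adjusted p = 0.221). Basement membrane genes were lower for 3 of 14 (COL4A1, COL4A2 and LAMB2) and higher for AGRN (median -0.14, adjusted p = 0.508). The 3 became 0 without the close stroma of heifer 3 or the parenchyma of heifer 3, 4 or 5, and 1 without the close stroma of heifer 5. COL4A1 did not pass without the close stroma of heifer 3 or 5 or the parenchyma of heifer 3, 4 or 5 (0.0667 to 0.158), COL4A2 without the close stroma of heifer 3 or the parenchyma of heifer 3, 4 or 5 (up to 0.0795), and LAMB2 with the heifer block (0.0621) or without any 1 sample but the close stroma of heifer 4 (0.0533 to 0.166). AGRN (1.03 ± 0.24, adjusted p = 0.0246) did not pass without the close stroma of heifer 3 (0.128) or the parenchyma of heifer 5 (0.0592). Among 12 IGF axis genes 0 passed by limma, against 1 higher and 4 lower at an unadjusted p under 0.05, 1 lower by edgeR, 1 higher and 3 lower by DESeq2 and 1 lower with the heifer block or without the close stroma of heifer 4 or the parenchyma of heifer 5. Median log2 was -0.15 over the list (adjusted p = 0.345; IGF1 0.02 ± 0.64). Of 26 WNT and Notch genes FZD4 and JAG1 were lower (2 higher and 2 lower when adjusted over the list alone, 1 higher and 4 lower with the heifer block), a balance that became 1 and 1 with library-total scaling and turned to 5 and 3 by DESeq2. Median log2 was 0.28 over the list (adjusted p = 0.495). Without the close stroma of heifer 4, 1 was higher. The count of lower members was 0 without the close stroma of heifer 3 and 1 without that of heifer 5 or any 1 parenchyma sample. FZD4 did not pass without the close stroma of heifer 3 (0.0895), and JAG1 without that of heifer 3 or 5 or any 1 parenchyma sample (0.0543 to 0.193). Stem and progenitor markers were higher for SOX10 and CD44 and lower for 3 of 16 (4 when adjusted over the list alone; median 0.07, mean -0.07, adjusted p = 0.837). The count of lower members was 0 without the close stroma of heifer 3 or the parenchyma of heifer 3 or 4, and 1 without that of heifer 5. The 2 higher members became 0 without the close stroma of heifer 3 or 5 and 1 without that of heifer 4 or the parenchyma of heifer 1, 3 or 5, and with the heifer block SOX10 alone passed (1 by edgeR, 2 with RLE scaling). SOX10 did not pass without the close stroma of heifer 3 (0.0806) or 5 (0.068). CD44 passed neither with the heifer block (0.0729) nor without any 1 sample but the parenchyma of heifer 4 (0.0813 to 0.128).

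Blood endothelium genes were lower for 11 of 17 members (15 when adjusted over the list alone, 4 without the close stroma of heifer 3), with TEK at 217 ± 31.9 against 900.8 ± 329.5, FLT1 at -1.08 ± 0.19 and PECAM1 at -1.18 ± 0.22. Median log2 was -1.08 over the list (adjusted p = 6.22e-12, and adjusted p = 0.223 with an estimated correlation). Lymphatic genes MMRN1 (-1.12 ± 0.23, adjusted p = 0.0121) and LYVE1 were lower of 9, and CCL21 passed as higher with the heifer block (0.0233; median -0.39, adjusted p = 0.205). LYVE1 did not pass when any 1 of the 7 samples was left out (0.0608 to 0.129). Of 13 smooth muscle and pericyte genes ABCC9 was lower (-1.53 ± 0.42, adjusted p = 0.0467; list median 0.25, mean 0, adjusted p = 0.877; 2 lower by edgeR with TMM and by DESeq2, 1 by edgeR with RLE, 0 with library-total scaling), but not without the close stroma of heifer 3 (0.229) or 5 (0.0941) or the parenchyma of heifer 3 (0.0882), 4 (0.124) or 5 (0.101). Of 4 skeletal muscle genes 0 passed by limma, against 1 lower when adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 without the close stroma of heifer 5 and 1 each by edgeR and DESeq2. Median log2 was 0.44 and mean -0.24 over the list (adjusted p = 0.849). Nerve and Schwann cell genes were lower for 4 of 11 (6 when adjusted over the list alone), with S100B at -1.51 ± 0.27. Median log2 was -0.88 over the list (adjusted p = 0.00465, and adjusted p = 0.21 with an estimated correlation). The count became 1 without the close stroma or the parenchyma of heifer 3 and 2 without the close stroma of heifer 5 or the parenchyma of heifer 4.

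T and NK cell genes were higher as a list (median 0.91, adjusted p = 5.90e-05, and adjusted p = 0.448 with an estimated correlation), with ZAP70 (826.8 ± 170.4 against 391.6 ± 85.2, 1.08 ± 0.21, adjusted p = 0.00784) and CD4 passing of 16 (7 when adjusted over the list alone, 5 by DESeq2). CD4 did not pass when any 1 of the 7 samples was left out (0.0504 to 0.144). B and plasma cell genes were higher as a list (median 0.71, adjusted p = 0.0129, and adjusted p = 0.473 with an estimated correlation), but not without the close stroma of heifer 3 (0.0607) or the parenchyma of heifer 5 (0.124). MZB1 of 15 passed (2.38 ± 0.53, adjusted p = 0.0187; 3 higher and 1 lower when adjusted over the list alone or by DESeq2, 1 lower with the heifer block, by edgeR or without the close stroma of heifer 4 or the parenchyma of heifer 5), but not without the close stroma of heifer 3 (0.0504), 4 (0.0526) or 5 (0.0544) or the parenchyma of heifer 3 (0.0532) or 5 (0.0565). By limma 0 of 16 macrophage genes passed, against 1 lower at an unadjusted p under 0.05, without the close stroma of heifer 4, by edgeR and by DESeq2. Median log2 was 0.28 over the list (adjusted p = 0.481). Mast cell and granulocyte genes were lower for 3 of 12, with CPA3 at -2.40 ± 0.45. Median log2 was -0.86 over the list (adjusted p = 0.0651, which was 0.00606 without the close stroma of heifer 4 and 0.0063 without the parenchyma of heifer 5, and adjusted p = 0.567 with an estimated correlation). The 3 became 1 without the close stroma of heifer 3 or 5 or the parenchyma of heifer 3 or 4. Among 16 interferon-stimulated genes 0 passed by limma, against 2 lower at an unadjusted p under 0.05, 0 by edgeR, 2 by DESeq2 and 1 with the heifer block. Median log2 was 0.23 over the list (adjusted p = 0.849). Immediate early and stress genes were lower for 3 of 19 (9 when adjusted over the list alone, 9 with the heifer block, 6 by edgeR, 9 by DESeq2, 8 without the close stroma of heifer 5), with KLF4 at -1.94 ± 0.29 and DUSP1 at 1378 ± 236.2 against 6938 ± 3892 (-2.16 ± 0.39). Median log2 was -1.02 over the list (adjusted p = 4.63e-05, and adjusted p = 0.448 with an estimated correlation). Of the untested erythrocyte list, HBA (-1.97 ± 0.99, adjusted p = 0.25) and HBB (-0.60 ± 1.25, adjusted p = 0.813) did not pass, and HBA passed without the parenchyma of heifer 5 (0.0201). With only the 2 groups compared in the fit, 12 T and NK cell and 3 luminal genes were higher, and 6 matrix protease, 2 nerve and 1 basement membrane genes lower.

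Close stroma differed from far stroma in all 22 luminal epithelium genes, which were higher there. KRT7 averaged 4121 ± 1311 in close stroma (n = 3) and 9.13 ± 4.17 in far stroma (n = 4; log2 8.72 ± 0.30, adjusted p = 1.1e-08), and LTF 27670 ± 13770 and 86.6 ± 18.9 (8.19 ± 0.47). By camera, the lists of T and NK cells and of B and plasma cells were also higher in close stroma, and the fibroblast and adipocyte lists were lower. These 4 calls did not hold with an estimated correlation (adjusted p = 0.254, 0.397, 0.418 and 0.416 in that order). The fibroblast gene DCN averaged 22300 ± 4732 against 59430 ± 8395 (-1.42 ± 0.24), and without the close stroma of heifer 4 or 5 the lower members fell from 13 to 3 in the fibroblast list and from 9 to 0 in the adipocyte list. In all, 1600 genes were higher and 875 lower (17% of 14596), of which 1396 and 466 differed at least 2-fold, and 1822 and 1003 passed with the heifer block. With library-total scaling 2805 were higher and 302 lower (90.3% higher against 64.6%, median shift 0.34). Without the close stroma of heifer 3, 4 or 5 the counts were 1940 and 1692, 1018 and 176, and 1083 and 240, and without the far stroma of heifer 4 or 5 they were 1368 and 532, and 1367 and 515.

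The largest rises in close stroma were in CYP11A1, SLC28A3, SPINT1, FOXA1, KRT15 and KRT7, in 3 of 3 heifers each. CYP11A1 averaged 1408 ± 1105 in close stroma and had a pooled ratio of 1590 (542 to 7690), and FOXA1 one of 1350 (373 to 11100). SLC28A3 differed by 9.09 ± 0.46, SPINT1 by 8.86 ± 0.58 and KRT15, a keratin of basal and progenitor cells, by 8.79 ± 0.49. Lowest in close stroma relative to far stroma were AOC1, CD209, CLEC4G, CCL24, RSPO3 and ECM1, in 3 of 3 heifers each. The lectin CD209 averaged 167.9 ± 127.3 against 1813 ± 1236 (-3.45 ± 0.61, adjusted p = 0.00194), the lectin CLEC4G differed by -3.35 ± 0.70, the eosinophil-attracting chemokine CCL24 by -3.19 ± 0.58, RSPO3, which enhances WNT signals, by -3.18 ± 0.63. The matrix protein ECM1 averaged 636.2 ± 587.9 against 4235 ± 2064. The amine oxidase AOC1 (-3.57 ± 0.84, adjusted p = 0.012) did not pass without the close stroma of heifer 4 (0.0667).

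All 22 luminal genes were higher in close stroma (median log2 6.76, or 7.20 with low-read members at their ratios; adjusted p = 7.88e-35), and the call held with an estimated correlation (adjusted p = 0.0176, and 0.0971 with the heifer block). EPCAM differed by 4.12 ± 0.38 and KRT8 by 7.79 ± 0.37. Basal and myoepithelial genes were higher for 14 of 19 (15 when adjusted over the list alone; median 5.14, adjusted p = 2.07e-16), which also held with an estimated correlation (adjusted p = 0.0315, and 0.118 with the heifer block). KRT5 averaged 2395 ± 1018 against 6.02 ± 2.48 (8.40 ± 0.35) and KRT14 had a pooled ratio of 432 (119 to 3580). Hormone receptors and responsive genes were higher for 10 of 17 (11 when adjusted over the list alone, 6 without the close stroma of heifer 5), such as GATA3 (3.94 ± 0.32) and AREG, an epidermal growth factor family ligand (4.20 ± 0.70). Median log2 was 2.40 over the list (adjusted p = 1.32e-05, and adjusted p = 0.219 with an estimated correlation). PGR was higher (2.40 ± 0.63, adjusted p = 0.0203), but not without the far stroma of heifer 4 (0.0527) or the close stroma of heifer 4 (0.121) or 5 (0.108), and ESR1 did not pass (0.64 ± 0.54, adjusted p = 0.444, higher in 2 of 3 heifers). Milk and secretory genes were higher for 8 of 18 (median 4.97, or 5.10 with low-read members at their ratios; adjusted p = 2.51e-06, and adjusted p = 0.397 with an estimated correlation), with CSN3 at 8953 ± 7105 against 52.4 ± 50.3.

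CSN2 was at 5600, 96.6 and 60900 in the close stroma of heifers 3, 4 and 5 and did not pass (log2 5.46, adjusted p = 0.132, and 0.0274 with the heifer block). PAEP was at 8080, 64.7 and 21200 there (5.26, adjusted p = 0.139, and 0.0278 with the heifer block). Among 22 cell cycle genes 0 passed by limma, against 6 higher at an unadjusted p under 0.05, 6 with the heifer block, 0 by edgeR, 0 by DESeq2, and 2 and 1 without the far stroma of heifer 1 and 3. The list (median 0.64, adjusted p = 0.0918) passed with the heifer block (0.00474), without the far stroma of heifer 3 (0.0317) and without the close stroma of heifer 4 (0.0342). Its adjusted p = 0.683 with an estimated correlation, and 0.557 with the block too.

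Adipocyte genes were lower in close stroma for 9 of 19 members (14 when adjusted over the list alone, 5 with library-total scaling, 5 by edgeR). Median log2 was -1.30 over the list (adjusted p = 2.90e-06, and adjusted p = 0.416 with an estimated correlation). That count was 0 without the close stroma of heifer 4 or 5, 3 without the far stroma of heifer 5 and 16 without the close stroma of heifer 3. PLIN1 (-1.30 ± 0.34, adjusted p = 0.0215) and LEP (-1.58 ± 0.41, adjusted p = 0.0203) did not pass without the close stroma of heifer 4 (0.0985 and 0.123) or 5 (0.0822 and 0.0934), and ADIPOQ (-0.87 ± 0.36, adjusted p = 0.117) passed without the close stroma of heifer 3 (0.0148). Fatty acid and triglyceride genes were lower for 3 of 17, with ME1 at -1.64 ± 0.37. Median log2 was -0.78 over the list (adjusted p = 0.0029, and adjusted p = 0.481 with an estimated correlation). The 3 became 1 without the far stroma of heifer 3, 4 or 5, the close stroma of heifer 4 or 5 by edgeR or with library-total scaling, 5 without the far stroma of heifer 1 and 6 without the close stroma of heifer 3. Fibroblast and collagen genes were lower for 13 of 21 (18 when adjusted over the list alone, 6 with library-total scaling, 7 by edgeR), such as THY1 (-1.43 ± 0.28) and fibrillin 1 (FBN1, -1.77 ± 0.38). Median log2 was -1.37 over the list (adjusted p = 3.21e-07, and adjusted p = 0.418 with an estimated correlation). The 13 became 7, 6 and 8 without the far stroma of heifer 1, 3 or 4 and 3 without the close stroma of heifer 4 or 5. COL1A1 (-2.28 ± 0.69, adjusted p = 0.0402) did not pass with the heifer block (0.0586), nor without the far stroma of heifer 1 (0.0604), 3 (0.0776) or 4 (0.0765) or the close stroma of heifer 4 (0.209) or 5 (0.168).

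Basement membrane genes were higher for AGRN (1.47 ± 0.24) and COL4A5 (1.86 ± 0.37) and lower for 3 of 14, such as LAMB2 (-1.43 ± 0.29), a balance that turned to 4 and 2 with library-total scaling (5 and 8 when adjusted over the list alone, 5 lower with the heifer block). Median log2 was -0.82 and mean -0.06 over the list (adjusted p = 0.214). The lower members were 8 without the close stroma of heifer 3 and 1 without that of heifer 4 or 5, and the higher ones 4 without the far stroma of heifer 1. Matrix proteases were higher for MMP9 and lower for 4 of 14, which turned to 2 and 1 with library-total scaling (5 lower when adjusted over the list alone, 2 lower by edgeR, 2 higher by DESeq2). Median log2 was -0.40 over the list (adjusted p = 0.105). The 4 became 0 without the close stroma of heifer 4 or 5, 1 without the far stroma of heifer 3 and 2 without that of heifer 4, and the list passed without the far stroma of heifer 5 (0.0329) or the close stroma of heifer 3 (0.0415; adjusted p = 0.529 with an estimated correlation). MMP9 (3.06 ± 0.93, adjusted p = 0.0414) did not pass without the far stroma of heifer 1 (0.0719), 3 (0.0539), 4 (0.057) or 5 (0.0545) or the close stroma of heifer 4 (0.179) or 5 (0.0945). Paracrine growth factors were higher for 3 and lower for 3 of 21, and for 4 and 0 with library-total scaling (4 lower when adjusted over the list alone; median -0.43, mean 0.04, adjusted p = 0.208), with NRG1 at 4.04 ± 0.52 and TGFA, at 0 reads in far stroma, at least 34.9-fold higher against a floor of 3 reads over the group. The 3 lower ones became 0 without the close stroma of heifer 4 or 5. IGF axis genes were higher for IRS1 and lower for 2 of 12, and for 2 and 1 with library-total scaling (3 lower when adjusted over the list alone, 5 without the close stroma of heifer 3, 1 without that of heifer 4 or 5; median -0.44, adjusted p = 0.109), with IGFBP6 at -2.42 ± 0.41 and IGF1 at 0.09 ± 0.64. IRS1 (0.80 ± 0.25, adjusted p = 0.0435) did not pass with the heifer block (0.0604) or without the far stroma of heifer 4 (0.103) or 5 (0.0991) or the close stroma of heifer 4 (0.238) or 5 (0.0815).

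WNT and Notch genes were higher for 11 of 26 (12 when adjusted over the list alone, 7 without the close stroma of heifer 4), such as WNT5B (2.57 ± 0.26), WNT6 (3.11 ± 0.38) and LEF1 (2.22 ± 0.34), and lower for WNT11 and the WNT inhibitor SFRP4 (5 lower when adjusted over the list alone, 4 by DESeq2, 1 with library-total scaling). The list passed (median 0.43, adjusted p = 0.0207, and adjusted p = 0.397 with an estimated correlation), but not without the far stroma of heifer 4 (0.0522). The 2 lower members were 4 without the far stroma of heifer 4 or the close stroma of heifer 3, and 1 without the far stroma of heifer 5 or the close stroma of heifer 4 or 5. Stem and progenitor markers were higher for SOX10 (5.37 ± 0.20) and SOX9 (4.50 ± 0.59) and lower for PROCR (-2.03 ± 0.37) and THY1 of 16 (4 lower when adjusted over the list alone, 5 without the close stroma of heifer 3). Median log2 was -0.13 and mean 0.24 over the list (camera direction down, adjusted p = 0.571).

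Blood endothelium genes were lower as a list (median -0.60, adjusted p = 5.54e-04, and adjusted p = 0.481 with an estimated correlation), while 0 of 17 members passed by limma, against 12 lower at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2. Without the close stroma of heifer 3, 9 members were lower, among them CLEC14A (0.00282), ESAM (0.00623) and PECAM1 (0.0107). Without the far stroma of heifer 1 or 3, 3 and 2 were lower. Lymphatic genes were lower for 3 of 9, with LYVE1 at -1.75 ± 0.39 and STAB1 at -1.44 ± 0.32. Median log2 was 0.13 and mean -0.21 over the list (adjusted p = 0.408). Smooth muscle and pericyte genes were higher for 2 and lower for 3 of 13, and for 3 and 1 with library-total scaling (1 higher by edgeR; median 0.11, camera direction down, adjusted p = 0.846), with MYH11 at 2.17 ± 0.35. The lower ones became 0 without the close stroma of heifer 4 or 5, and the higher ones 1 without either of these or the far stroma of heifer 3 or 5. Of 4 skeletal muscle genes 0 passed by limma, against 1 higher at an unadjusted p under 0.05, 1 without the close stroma of heifer 3, 0 by edgeR and 1 by DESeq2. Median log2 was 0.21 over the list (adjusted p = 0.735). Nerve and Schwann cell genes were higher for ERBB3 (5.31 ± 0.37) and MBP and lower for PMP22 (-1.25 ± 0.24; 2 lower with the heifer block or without the close stroma of heifer 3) of 11. Median log2 was -0.39 and mean 0.24 over the list (adjusted p = 0.682). MBP (1.69 ± 0.41, adjusted p = 0.0145) did not pass without the close stroma of heifer 4 (0.0922).

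All 16 T and NK cell genes were higher in close stroma (median 2.49, adjusted p = 7.83e-12, and adjusted p = 0.254 with an estimated correlation), with CD3E at 988.4 ± 84.9 against 144.7 ± 102.4 (3.01 ± 0.38) and ZAP70 at 2.23 ± 0.21. B and plasma cell genes were higher for 9 of 15 (10 higher and 2 lower when adjusted over the list alone, 5 higher without the close stroma of heifer 5), such as CD79A (3.97 ± 0.39), and lower for CR2 (-2.43), which did not pass without the far stroma of heifer 4 or the close stroma of heifer 4 or 5. Median log2 was 2.25 over the list (adjusted p = 5.54e-04, and adjusted p = 0.397 with an estimated correlation). Macrophage and myeloid genes were higher for LYZ and lower for CD163 (-2.22 ± 0.50) and C1QA (-1.73 ± 0.44) of 16 (4 lower when adjusted over the list alone, by edgeR or by DESeq2). CD163 did not pass without the close stroma of heifer 4 (0.0533), nor C1QA without that of heifer 4 (0.0703) or 5 (0.0824). The list passed (median -0.65, adjusted p = 0.0222, and adjusted p = 0.653 with an estimated correlation), but not with the heifer block (0.052) or without the far stroma of heifer 1 (0.129) or 4 (0.106). The 2 lower members were 7 without the far stroma of heifer 5, 4 without the close stroma of heifer 3, and 0 and 1 without that of heifer 4 and 5. LYZ (1.71 ± 0.44, adjusted p = 0.0197) did not pass without the close stroma of heifer 4 (0.0733). Mast cell and granulocyte genes were lower for CPA3 and GATA2 of 12 (3 when adjusted over the list alone, 0 with the heifer block or library-total scaling). Median log2 was -0.83 over the list (adjusted p = 0.109, 0.034 without the close stroma of heifer 5, and adjusted p = 0.621 with an estimated correlation). That count was 0 without the far stroma of heifer 1 or 4 or the close stroma of heifer 4, 1 without the close stroma of heifer 5 and 5 without that of heifer 3. CPA3 passed neither with the heifer block (0.053) nor without the far stroma of heifer 1 (0.057) or 4 (0.079) or the close stroma of heifer 4 (0.164), and GATA2 neither with the block (0.0722) nor without the far stroma of heifer 1, 4 or 5 or the close stroma of heifer 4 or 5 (0.0599 to 0.18). Interferon-stimulated genes were higher for IFI44L (2.33 ± 0.27), MX2 (2.72 ± 0.35) and IFI44 (2.03 ± 0.32) of 16 (4 when adjusted over the list alone, 5 with library-total scaling), and 2 were lower without the close stroma of heifer 3. Median log2 was 0.36 over the list (adjusted p = 0.144, 0.034 without the close stroma of heifer 5, and adjusted p = 0.653 with an estimated correlation). Immediate early and stress genes were higher for EGR2 and EGR3 and lower for KLF4 of 19 (1 higher and 1 lower when adjusted over the list alone). Median log2 was -0.03 and mean 0.22 over the list (adjusted p = 0.977). The 2 higher ones became 0 without the close stroma of heifer 3 or 4, 1 without the far stroma of heifer 4 or 5 and 4 without the close stroma of heifer 5. EGR2 did not pass without the close stroma of heifer 3 (0.0565) or 4 (0.0906), nor EGR3 without the far stroma of heifer 4 or 5 or any 1 close stroma sample (0.0748 to 0.124), and KLF4 (-1.07 ± 0.29, adjusted p = 0.0255) did not pass without the far stroma of heifer 4 (0.065) or the close stroma of heifer 4 (0.0542) or 5 (0.135). Of the untested erythrocyte list, HBA (-0.97 ± 0.99, adjusted p = 0.527) and HBB (0.32 ± 1.25, adjusted p = 0.885) did not pass. With only the 2 groups compared in the fit, the lower members numbered 0 for adipocytes, mast cells and the stress list, 1 for fatty acids, basement membrane, paracrine factors, WNT and Notch, smooth muscle and macrophages, 2 for matrix proteases and 7 for fibroblasts. The stress list and macrophages then had 0 higher members. Without heifer 1, 6 fibroblast, 3 blood endothelium, 1 matrix protease and 0 mast cell genes were lower, and basement membrane genes turned to 4 higher and 3 lower.

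Close stroma lay between the other regions on the log2 scale. Over the 4703 genes called with at least a 2-fold difference between parenchyma and far stroma, its position from far stroma (0) to parenchyma (1) was 0.28, 0.74 and 0.70 in heifers 3, 4 and 5 (mean 0.57 ± 0.25 SD, n = 3). It was 0.69 ± 0.20 over the 2568 genes higher in parenchyma and 0.45 ± 0.27 over the 2135 lower ones. For the luminal list it was 0.84, 0.99 and 0.88 (0.90 ± 0.08) and for the adipocyte list 0.04, 0.33 and 0.22 (0.20 ± 0.15), so that luminal genes stood nearer to parenchyma than adipocyte genes did in 3 of 3 heifers. Choosing genes by the difference of the end regions biases these fractions, and the log2 scale places a small share of a strongly expressed transcript far from 0.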

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

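The test for a sample that stands apart was fixed before the data were examined, and no test of a cause was run for the values in this part. In groups of 4, the gap between the highest or lowest sample and its nearest neighbour was divided by the range of the group, and 7 of 124 values lay above Dixon's 95% critical value. Chance alone gives about 1 in 20. The groups of 3 close stroma samples were not tested.

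Among mean list scores on the log2(value + 1) scale, the B and plasma cell list stood apart in the far stroma of heifer 1 (ratio 0.965, 4.38 against 3.87 to 3.89). In the parenchyma of heifer 1, the adipocyte list was higher than in the other heifers (0.84, 7.22 against 6.72 to 6.8), as was the list of stem and progenitor markers (0.906, 9.46 against 9.09 to 9.13). The erythrocyte list, HBA and HBB, was higher in the parenchyma of heifer 5 (0.864, 5.49 against 0.404 to 1.1).

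Among named genes, the epithelial protease inhibitor SPINT1 was lower in the parenchyma of heifer 1 (0.848, 10.4 against 11.3 to 11.5). The lipid droplet gene CIDEC was lower in the parenchyma of heifer 3 (0.875, 6.26 against 6.84 to 6.92), and so was the calcium channel gene CACNA1G (0.84, 7.86 against 8.2 to 8.27).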

How the results depend on the processing

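Chosen only after the data were seen were edgeR, DESeq2, TMM and library-total scaling, and limma without the trend. No named gene that was called before or under an alternative changed its sign there, and no gene was called in opposite directions. Balances of higher and lower calls did turn for parenchyma against far stroma by edgeR with TMM scaling, though not with RLE. They also turned for the lists named with the results under library-total scaling, DESeq2 or with samples left out. Of the values for counts, list counts and position, 157 stayed within 1.5 times or within their spread and 46 moved. Of 7854 values of named genes, 7295 kept their call, 417 lost it and 142 gained one. Genes higher in parenchyma than in close stroma (295) numbered 496 with the heifer block, 622 with only the 2 groups compared, 183 without heifer 1, 32 at an adjusted p under 0.01, 158 at the authors' thresholds and 818 by DESeq2. Genes lower there (744) numbered 338 at 0.01 and 1222 by DESeq2. Genes higher in close than in far stroma (1600) numbered 1030 at 0.01 and 2805 with library-total scaling. Genes lower there (875) numbered 396 with only the 2 groups, 190 at 0.01, 454 at the authors' thresholds and 302 with library-total scaling. Between parenchyma and far stroma (3805 higher, 3501 lower), 2322 and 2018 passed the authors' thresholds, and library-total scaling gave 6366 and 2093. Leaving out 1 sample at a time gave 3260 to 3824 higher and 3035 to 3481 lower genes in parenchyma against far stroma, 53 to 340 and 326 to 912 against close stroma, and 1018 to 1940 and 176 to 1692 in close against far stroma. Lists called by camera at the preset correlation numbered 7 higher and 6 lower, 5 and 6, and 7 and 5 in the comparisons in that order. With an estimated correlation they numbered 0 and 0, 0 and 0, and 2 and 0, and by fry 10 and 11, 1 and 5, and 7 and 2. Leaving out 1 sample gave 2 to 5 higher lists in parenchyma against close stroma. The position of close stroma (0.57) was 0.90 over the luminal list alone and 0.20 over the adipocyte list alone. It was 0.49 to 0.72 with 1 heifer left out of the mean and the genes kept as chosen. Stricter thresholds give fewer calls by construction, and the cause was not tested for the other moved values. Beyond the calls and counts given with the results, the heifer block changed no call of a list or of a gene whose values are printed there. The planned comparison with fold changes of the authors was not run, since none were used here, and the alternatives planned for raw counts were run on the recovered reads. Genes with a few reads in 1 region have wide intervals, such as 596 to 17800 for the FOXA1 ratio.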

Other observations

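The counts over other splits of the samples were planned, and all other tests in this part were chosen only after the results were seen, as were the genes named. The homeobox gene EN1 averaged 4.00 normalised counts in parenchyma against 197 in far stroma (log2 -5.25 ± 0.43, limma adjusted p = 1.1e-06). The transcription factor genes MSX1 (-2.79 ± 0.32), HOXB7 (-2.57 ± 0.30), HOXC10 (-2.34 ± 0.26) and TBX15 (-1.85 ± 0.24) were also lower, and PITX1 was at 0 against 41.3. IRX3 (2.61 ± 0.28), IRX5 (2.63 ± 0.26), MSX2 (2.57 ± 0.39) and TBX3 (1.57 ± 0.28), which acts in mammary development, were higher in parenchyma. Of 8 genes known from brown and beige fat, which were picked without a fixed list or a set test, CIDEA (-6.45 ± 0.66), COX8B (-5.46 ± 0.73), CKB (-2.86 ± 0.45), PRDM16 (-1.34 ± 0.39) and COX7A1 (-0.97 ± 0.23) were lower in parenchyma. DIO2, which activates thyroid hormone, was higher at 31.2 against 0.978, and PPARGC1A (-1.02 ± 0.46) and EBF2 (-0.90 ± 0.50) did not pass.

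The serum amyloid gene M-SAA3.2 averaged 5160 in parenchyma against 9.54 in far stroma (log2 8.80 ± 0.60), the siderophore-binding LCN2 1030 against 6.19 (6.88 ± 0.91) and the peptidoglycan receptor PGLYRP1 270 against 2.32 (6.19 ± 0.64). The chemokines CXCL10 (5.42 ± 0.66) and CCL5 (3.49 ± 0.31) and the class II antigen presentation genes CD74 (1.93 ± 0.28), BOLA-DRA (1.52 ± 0.26) and CIITA (1.78 ± 0.24) were higher too. The neutrophil genes S100A8 (-0.54 ± 0.90) and S100A9 (-0.67 ± 0.94) did not pass. CD209 (-6.35 ± 0.57), CLEC4G (-5.88 ± 0.64) and CCL24 (-5.30 ± 0.53) were lower in parenchyma. Of 4 other genes of macrophage subsets, CD163 (-3.77 ± 0.46) and LYVE1 (-3.21 ± 0.36), which lymphatic vessels also express, were lower, and MRC1 (-0.81 ± 0.40) and CD68 (-0.47 ± 0.32) did not pass. Of the partners of CYP11A1 in steroid synthesis, STAR did not pass (1.06 ± 0.55), FDX1 was lower (-2.14 ± 0.22) and FDXR did not pass (0.30 ± 0.29).

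In each comparison, 1 of 35 splits of the samples, the real one, gave as many genes. That share is under 0.05, which would speak against chance as their source only if the samples were exchangeable. Parenchyma against far stroma called 7306 genes and the highest other split 0, parenchyma against close stroma 1039 and 1, and close against far stroma 2475 and 767. The heifer numbers pair the samples, however, and the 8 splits that part every heifer's pair are too few for a share under 0.05. The highest others among them gave 0, 0 and 767, and the remaining splits set samples of a heifer together. The split with 767 genes set the far stroma of heifers 3, 4 and 5 against the far stroma of heifer 1 and the close stroma.

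Close stroma may be a mixture of parenchyma and far stroma. On the linear scale, its share of parenchyma signal in heifers 3, 4 and 5 was 0.36, 0.95 and 0.49 by the luminal list and 0.22, 0.79 and 0.69 by the adipocyte list, a mean difference of 0.03 ± 0.21. The luminal share exceeded the cell cycle share by 0.27 ± 0.35, the blood endothelium share by 0.18 ± 0.45, the T and NK cell share by 0.11 ± 0.26 and the basal share by 0 ± 0.14, each within its spread, and the B and plasma cell share by 0.10 ± 0.09, in 3 of 3 heifers, where it was 0.17, 0.94 and 0.39 over 9 genes. By limma, 0 genes lay beyond both other regions after adjustment, against 42 lower and 5 higher at an unadjusted p under 0.05, and CHRD, ANO4, DNM1 and CD248 were the 4 called lower than both in the separate comparisons. With 3 heifers, 6 lists compared and such spreads, neither a mixture nor a region with its own makeup is excluded.

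All 16 T and NK cell genes were higher in parenchyma than in far stroma (median log2 3.34, quartiles 2.73 to 3.87, adjusted p = 0.277 for the list with an estimated correlation). A lower share of fat cells would raise the genes of every other cell type alike, but the blood endothelium median was -1.61 (quartiles -2.10 to -1.25) and the macrophage median -0.39. More blood in the parenchyma pieces cannot be excluded by the sum of HBA and HBB, at most 0.057 of CD3E in a parenchyma sample. How much haemoglobin mRNA the blood of these animals holds was not measured. In heifers 1, 3 and 4 both genes were lower in parenchyma than in far stroma. These values were too low to gauge blood (HBA at 0, 0.81 and 0 against 13.7, 8.4 and 37.2). In heifer 5, HBB was higher in parenchyma (80.6 against 4.84, with CD3E at 1820 against 77.4), and HBB did not pass overall (adjusted p = 0.859). More T cells in the tissue, which may lie in or beside the epithelium, and higher expression per cell stay open and were not tested.

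UVRAG, an autophagy gene, was lower in parenchyma (log2 -7.54), inside the range of the adipocyte list (-9.16 to -1.26), with means of 246 against 48200. Its 5 partners BECN1, PIK3C3, PIK3R4, ATG14 and RUBCN had a median of -0.05 and a range of -0.53 to 1.33. Its immediate neighbours in the ARS-UCD2.0 table are DGAT2, a triglyceride synthesis gene of fat cells, and WNT11. WNT11 has its own entry (89.7 against 500.2, log2 -2.39), and 0 entries of the deposited table are named DGAT2. A candidate explanation is that reads of DGAT2 were counted under UVRAG, and regulation of UVRAG stays open.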
